A study of Drosophila melanogaster with 5 samples.

How the data were processed

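Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used on eye imaginal discs of third-instar Drosophila melanogaster larvae. Of 5 samples, 3 were immunoprecipitations, with antibodies against Yorkie (Yki), Scalloped (Sd) and RNA polymerase II (Pol II), and 2 were input DNA. Per the labels, discs were fixed in 2% formaldehyde for 30 minutes, and each immunoprecipitation used 10 µg of antibody on chromatin from about 300 discs. The Yki and Sd samples came from discs expressing the Yki S168A form under GMR-Gal4, and the Pol II sample from discs expressing Yki-V5 under the same driver. Antibody and genotype therefore differ together in every comparison with Pol II. Each antibody had 1 library, so no replicate spread exists, and no p-value is given across peaks.

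The files analysed were 3 peak lists, 1 per immunoprecipitation. Per the submitters' processing notes, CASAVA 1.8.2, Bowtie and MACS2 were used with genome build dm3. The versions of Bowtie and MACS2, their parameters, the control library and any read filter are not given in the sources used here. Each line gives a chromosome, a start, an end, a peak name and 1 value. The deposited value behaves as a −log10 q value from the authors' peak caller: the smallest value was 3.01 in the Yki list, 2.00 in the Sd list and 3.01 in the Pol II list, just above whole numbers. No header states the unit, and this reading rests on those minima. The value is called the score below. It depends on the depth of its library, so it ranked peaks within 1 list and was not compared between lists. If the score is a −log10 q value, the Sd list was called with a looser limit than the other lists; of its 2557 peaks, 2432 had a score of at least 3. Peak names ran without a gap from 1 to the last peak in each list, and no peaks of a list overlapped each other. Read depth is unknown, because the lists hold neither counts nor coverage. The values of the input libraries were not analysed here. The number of peaks called from a library rises with its depth and enrichment, which could change every overlap below.

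Coordinates are those of the lists, on dm3, written 1-based. The gene table used here is on Release 6 of the genome and no dm3 sequence or annotation was used, so peaks were not assigned to genes. The planned work on transcription start sites, fixed gene lists and motifs (3 results) was therefore not run. Peaks and windows to be named were fixed before the data were examined. They are the 10 peaks of highest score in each list, the 10 highest-scoring Yki peaks that overlap an Sd peak, the 10 highest-scoring Sd peaks without a Yki peak, and the 5 windows of 100 kb with the most Yki peaks and with the most Sd peaks. Ties were broken by chromosome and start. Any other peak named was chosen after its values were seen.

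Peaks of different lists were counted as overlapping when they shared at least 1 bp. Percents carry exact Clopper-Pearson 95% intervals, which treat peaks as independent and say nothing about differences between libraries; for a count of 0, the limit given is 3 counts of the total. For the level expected by chance, 1 list was moved around each chromosome by a common random offset (1000 circular shifts), which keeps the number, widths and spacing of its peaks. Shifted peaks can land anywhere on the chromosome, so this level does not allow for chromatin accessibility or gene density. The length of a chromosome was taken as the last peak end in any list. Deciles divide a list into 10 equal parts by score or width, with decile 10 the highest. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Overlaps of 0, 50 and 90% of the 2557 Sd peaks were planted in simulated peaks drawn with the numbers and widths of the Sd and Yki lists. Peaks were placed at random, without the clustering of the real lists, and simulated Yki peaks that overlapped an earlier one were dropped. The planted overlaps were recovered as -0.091, 50.2 and 90.1% (mean of 10 simulations each). For this, the shifted level was subtracted and the result divided by the share of peaks left outside that level. Alternatives fixed before the data were examined were an overlap of at least 50% of the shorter peak, the upper 50% of each list by score, lists cut to equal length, peaks reduced to their central 200 bp, the chromosome arms 2L, 2R, 3L, 3R, 4 and X alone, and random placement in place of shifts. A score limit of 3 for Sd, a gap of 1 kb to Pol II, comparisons within deciles of Yki score, and Sd overlap by score within deciles of Yki width were added after seeing the data.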

Results

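Genome-wide binding was mapped for 3 proteins in eye imaginal discs, the larval tissue that forms the adult eye. Yki is the transcriptional coactivator at the end of the Hippo growth-control pathway and has no DNA-binding domain of its own. Sd is the TEAD-family DNA-binding protein that partners with it. Pol II marks transcribed and promoter-paused genes. Discs overexpressed Yki under GMR-Gal4, a driver active in the posterior eye disc, and the labels describe ectopic cell proliferation. S168A removes a phosphorylation site through which the Hippo pathway restrains Yki.

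The Yki list held 11679 peaks, the Sd list 2557 and the Pol II list 10105. Median width was 403 bp for Yki (quartiles 298 and 588), 270 bp for Sd (229 and 342) and 423 bp for Pol II (309 and 686). The peaks covered 5.79 Mb for Yki, 0.792 Mb for Sd and 6.34 Mb for Pol II. Pol II peaks reached the greatest width, with 360 wider than 2 kb against 43 for Yki and 0 for Sd. On heterochromatic or unplaced sequence lay 1.14% of Yki peaks, 1.92% of Sd peaks and 1.54% of Pol II peaks. Yki density ran from 80.9 peaks per Mb on chromosome 4 to 103 on 2R. Sd density was between 19.7 and 22.2 peaks per Mb on 2L, 2R, 3L, 3R and X, and 39.3 on chromosome 4. Read depth behind the lists is unknown, and each list came from 1 library.

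The first comparison asked where Yki and Sd sit relative to each other in discs of the same genotype. Nearly every Sd peak fell on a Yki peak: 2499 of 2557, or 97.7% (95% interval 97.1 to 98.3), against a mean of 7.39% and a highest value of 9.35% in 1000 circular shifts. The reverse share was smaller. Of 11679 Yki peaks, 2345 overlapped an Sd peak, or 20.1% (19.4 to 20.8), against a shifted mean of 1.62% and a highest of 2.17%. The remaining 9334 Yki peaks had no Sd peak. The Sd peak lay wholly inside the Yki peak in 93.4% of 2503 overlapping pairs, and the centres were a median of 60.5 bp apart. Of the 2345 Yki peaks with Sd, 2210 held 1 Sd peak and 135 held 2 or more. The peak with the most was a 3342 bp Yki region on 2L from 12004565 to 12007906, which held 5 Sd peaks and no Pol II peak. When all lists were cut to the 2557 highest-scoring peaks, the share of Sd peaks on a Yki peak was 56.6%, and with equal lists 52.0% of Yki peaks overlapped an Sd peak.

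**Figure D1:**
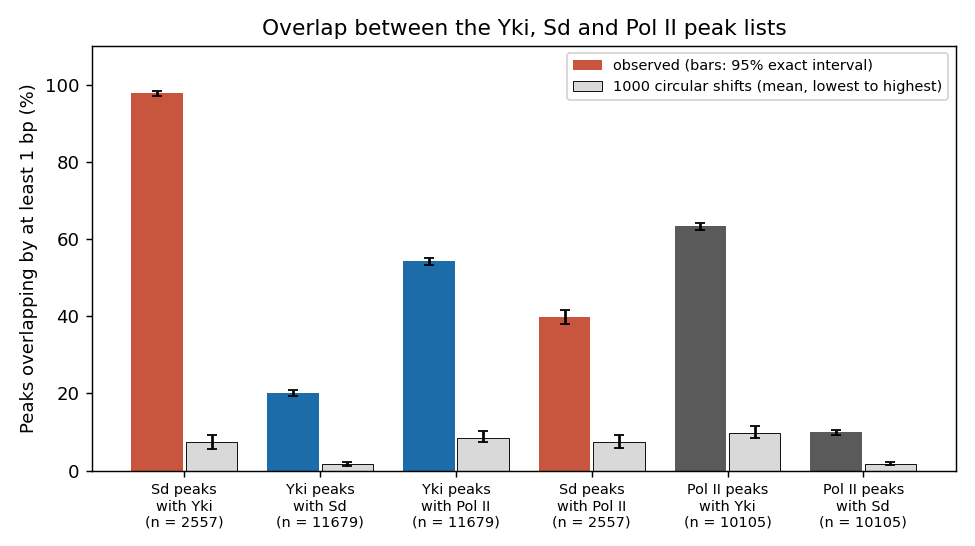
Percent of peaks in each list that overlap a peak of another list by at least 1 bp (coloured bars, with exact 95% intervals), beside the mean of 1000 circular shifts (grey bars, whiskers from the lowest to the highest shift). Sd peaks on Yki peaks stand at 97.7% against a shifted mean of 7.39%, and each of the 6 observed shares lies above the highest shift.

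The share of Yki peaks with an Sd peak rose with Yki score, though 358 of the 1168 peaks in the highest decile had none. In the lowest decile of Yki score 2.05% of peaks overlapped an Sd peak (1.32 to 3.04), in decile 5 12.2%, in decile 9 38.3% and in the highest decile 69.3% (66.6 to 72.0). Of the 100 highest Yki peaks 97 had an Sd peak, and of the highest 500 435 did. Yki peaks with Sd had a median score of 41.3 (n = 2345) and those without one of 18.5 (n = 9334). A Yki peak with Sd outscored one without in 81.0% of pairs. Shared Yki peaks were also wider, with a median of 582 bp against 367 bp. Within deciles of Yki width the rise was smaller, from 6.50% in the lowest to 53.7% in the highest score decile. Across the 2345 shared Yki peaks, which are not independent replicates, the Yki score and the highest Sd score had a Spearman rho of 0.42 and a Pearson r of 0.50.

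All 10 highest-scoring Yki peaks overlapped an Sd peak, so they are also the 10 highest shared peaks. The first was a 526 bp peak on X from 17645618 to 17646143 with a score of 128, which also overlapped Pol II. The next were on 3L from 17589909 to 17590491 (score 127), on X from 20631301 to 20631884 (124), on 2R from 21070326 to 21070958 (122) and on 3R from 8903962 to 8904402 (120.4). These 4 had no Pol II peak. The Sd peaks inside all 5 of these sites carried the highest score in the Sd list, 16.3, which 25 Sd peaks shared. A 1910 bp Yki peak on X from 15998269 to 16000178 (score 116) held an Sd peak of the same top score and overlapped 1 of the 2 Pol II peaks tied for the highest score, at 15998438 to 15999134. Of the 10 highest Yki peaks, 4 overlapped Pol II. The first 10 Sd peaks in genome order among the 25 tied at the top all overlapped a Yki peak, and 2 of them, on 3LHet from 1396707 to 1397109 and on 4 from 380333 to 380968, overlapped Pol II.

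Only 58 Sd peaks had no Yki peak. They had a median score of 5.95 and a median width of 221 bp, against 6.87 and 271 bp for Sd peaks on Yki. Of the 58, 20 lay within 1 kb of a Yki peak, 4 overlapped Pol II, and 25 were on 3R. That arm, singled out after the values were seen, held 566 of all Sd peaks, or 22.1%. The highest was on X from 15570224 to 15570444 (score 10.8), 495 bp from the nearest Yki peak. The second, on 3R from 685142 to 685374 (9.77), was 6598 bp from one. None of the 10 highest overlapped Pol II.

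The second comparison set Yki and Sd against Pol II, mapped in discs of the other genotype. Pol II overlapped 6336 Yki peaks, or 54.3% (53.3 to 55.2), against a shifted mean of 8.51% and a highest of 10.4%. It overlapped 1017 Sd peaks, or 39.8% (37.9 to 41.7), against a shifted mean of 7.41% and a highest of 9.35%. With every peak reduced to its central 200 bp, the shares on Pol II were 29.2% for Yki and 18.5% for Sd, and with lists of equal length 32.2 and 18.8%. Seen from Pol II, 63.3% of its 10105 peaks overlapped a Yki peak and 9.90% an Sd peak. Of the 1000 Pol II peaks with an Sd peak, 999 also had a Yki peak.

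Yki presence followed Pol II score steeply. A Yki peak overlapped 16.4% of Pol II peaks in the lowest decile of Pol II score (14.2 to 18.8), 67.1% in decile 5 and 95.6% in the highest decile (94.2 to 96.8). For Sd the corresponding shares were 3.86, 8.70 and 21.6%. Median Pol II width also rose, from 277 bp in the lowest score decile to 649 bp in the highest, and was not held constant here. From the narrowest to the widest decile of Pol II peaks, Yki overlap rose from 34.1 to 79.1% and Sd overlap from 4.75 to 23.6%. All 10 highest Pol II peaks had a Yki peak and none had an Sd peak. The first of these were on X from 14968483 to 14970430 and from 15998438 to 15999134, both with a score of 155, and on 3L from 7149734 to 7150373 (154). Pol II peaks wider than 2 kb overlapped Yki in 86.4% of 360 cases and Sd in 26.9%, against 62.4% and 9.27% of 9745 narrower peaks. Wider peaks meet more of any list by length alone. No shifted level was computed for these width classes, so enrichment beyond width was not tested. The widest, chosen after its values were seen, spanned 15.5 kb on 3L from 628280 to 643758 and held 4 Yki and 3 Sd peaks. The next widest, 15.3 kb on 2R from 5522285 to 5537618, held 0 of either.

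**Figure D2:**
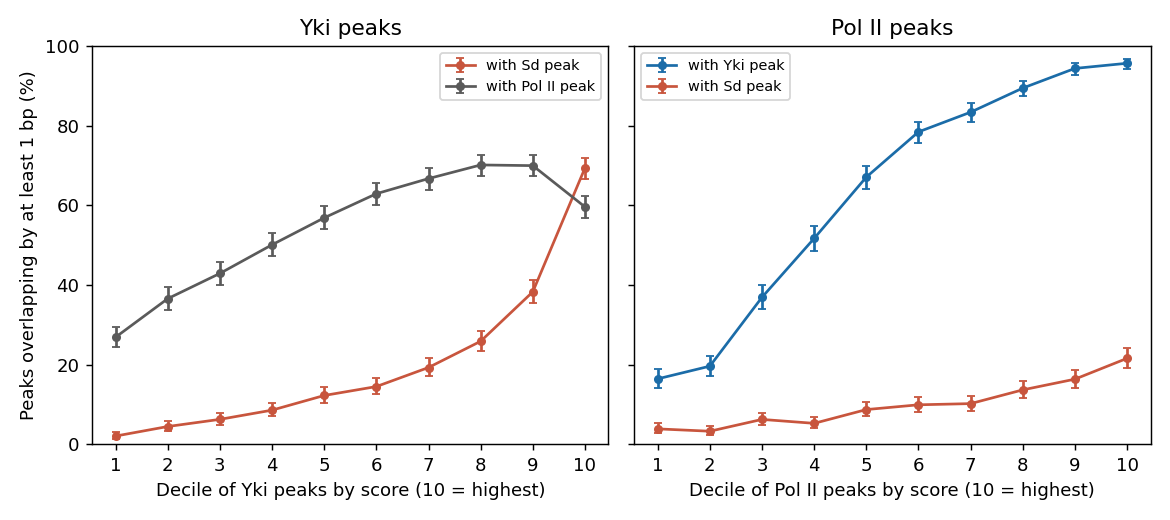
Percent of Yki peaks with an Sd or Pol II peak (left) and of Pol II peaks with a Yki or Sd peak (right), by decile of the score of the list on the x axis, with exact 95% intervals. Sd overlap of Yki peaks climbs to 69.3% in decile 10, where Pol II overlap is 59.6% after 69.9% in decile 9; Yki overlap of Pol II peaks climbs from 16.4 to 95.6%.

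Yki sites shared with Sd carried Pol II less often than Yki sites without Sd. Pol II overlapped 46.7% of Yki peaks with Sd (44.7 to 48.7, n = 2345) and 56.1% of those without (55.1 to 57.2, n = 9334), a difference of -9.45 percentage points. In 1000 circular shifts of the Sd peaks, which on average left 189 Yki peaks with Sd, the difference averaged 1.98 and was at or below the observed one in 1 shift. Between peaks of like width or score the difference was larger. With each decile counted equally, the difference averaged -22.2 points within deciles of Yki width and -26.2 within deciles of Yki score. It was below 0 in each of the 10 deciles of either. Score deciles 8, 9 and 10, which held the most peaks with Sd (302, 447 and 810), gave -19.1, -18.7 and -17.6 points. The largest difference, -41.7 points, was in score decile 5 with 143 such peaks. Median Yki score was 45.7 with both Sd and Pol II, 35.4 with Sd only, 22.8 with Pol II only and 13.2 with neither. Median width fell in the same order, from 636 to 327 bp. Comparing within deciles of a measure that rises with both overlaps can by itself lower the Pol II share of peaks with Sd. The larger differences are therefore not a cleaner estimate than -9.45. The smallest decile group held 23 peaks with Sd. In the highest score decile, Pol II overlapped 54.2% of 810 Yki peaks with Sd (50.7 to 57.7) and 71.8% of 358 without (66.8 to 76.4). Of the 100 highest Yki peaks, 31.0% overlapped Pol II. Among Yki peaks outside Pol II peaks, the nearest Pol II peak was a median of 6382 bp away from those with Sd (n = 1250) and 4733 bp from those without (n = 4093). Both were nearer than shifted Yki peaks, whose median averaged 9324 bp (7940 to 10107 in 100 shifts). These distances were not compared within deciles of score or width. Antibody and genotype differ together between these lists, so the Pol II overlap could not be compared within 1 genotype.

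**Figure D3:**
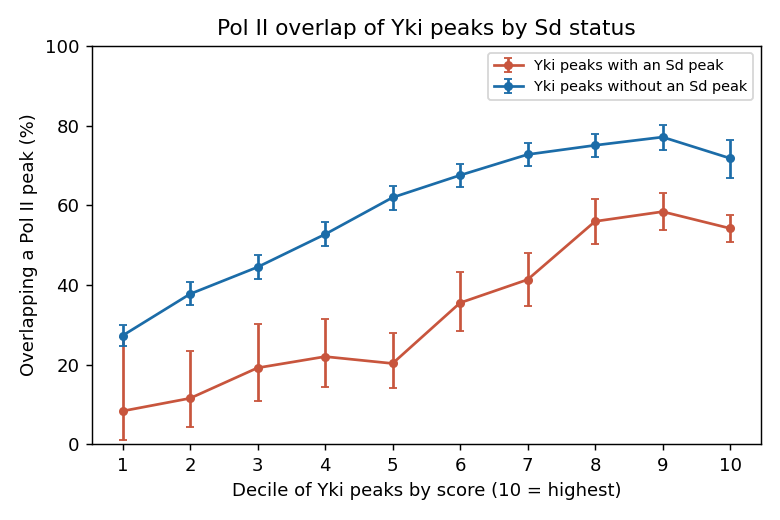
Percent of Yki peaks that overlap a Pol II peak, by decile of Yki score, for Yki peaks with and without an Sd peak, with exact 95% intervals. Peaks with Sd lie lower in all 10 deciles, with 54.2 against 71.8% in decile 10.

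Peak counts of the 3 proteins also went together by region. This partly restates the overlaps above, since overlapping peaks mostly fall in the same window. Across 1206 windows of 100 kb on the 6 arms, which are not independent replicates, peak counts had a Spearman rho of 0.61 for Yki and Sd (Pearson r 0.59), 0.72 for Yki and Pol II (0.67) and 0.37 for Sd and Pol II (0.30). The highest rho in 1000 shifts was 0.22, 0.23 and 0.13. A window held a median of 9 Yki, 2 Sd and 7 Pol II peaks. Windows without a peak, which can also raise rho, numbered 61 for Yki, 282 for Sd and 100 for Pol II. The most Yki peaks, 34, lay on 3R from 17400001 to 17500000, with 12 Sd and 16 Pol II peaks. The next windows were on 3L from 10700001 to 10800000 with 31 Yki, 7 Sd and 2 Pol II peaks, on 3R from 12000001 to 12100000 with 30, 7 and 29, on 2R from 6400001 to 6500000 with 29, 7 and 26, and on 2R from 14100001 to 14200000 with 28, 10 and 11. The most Sd peaks, 15, lay on 3L from 600001 to 700000, with 23 Yki and 13 Pol II peaks, 1 of which was the 15.5 kb Pol II region. It was followed by 2L from 400001 to 500000 with 12 Sd, 15 Yki and 24 Pol II peaks, by the 3R window already named, and by 3L from 3300001 to 3400000 and from 14600001 to 14700000 with 11 Sd peaks each.

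**Figure D4:**
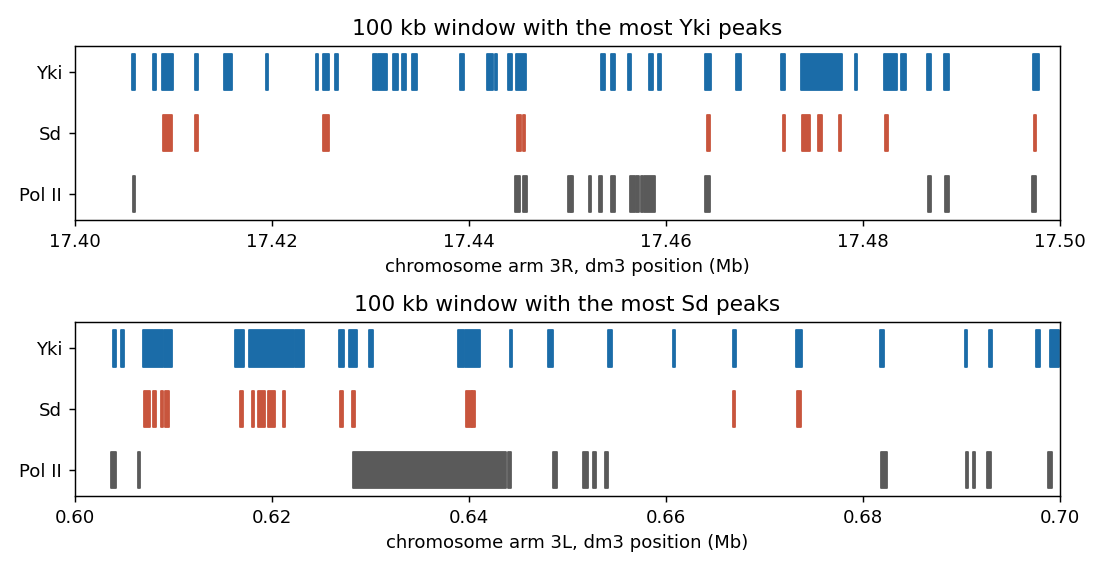
Yki, Sd and Pol II peaks drawn to scale in the 100 kb windows with the most Yki peaks (top, 3R) and the most Sd peaks (bottom, 3L); the x axis is the dm3 position in Mb and each block is 1 peak. The 3R window holds 34 Yki, 12 Sd and 16 Pol II peaks, and the 3L window 23, 15 and 13.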

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

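Nothing was replicated, so stability was judged against the exact 95% interval of each share (for the difference in Pol II overlap, a 95% normal-approximation interval of the difference), a narrow standard. Every overlap alternative kept the observed share above its shifted mean, by 5.21 to 28.0 times. The Sd score limit of 3, the 1 kb gap, the Pol II comparison within score deciles and the Sd overlap by score within width deciles were chosen after seeing the data. Requiring 50% of the shorter peak, keeping the arms alone and, except for the share of Yki peaks with Sd (19.2%), the Sd score limit of 3 left the shares of Sd and Yki peaks on each other within their intervals; the 50% rule gave 48.4% of Yki and 33.8% of Sd peaks on Pol II. With the upper 50% of each list by score (5843 Yki, 1303 Sd and 5054 Pol II peaks), 87.9% of Sd peaks overlapped Yki, 19.0% of Yki peaks overlapped Sd, and 52.0% of Yki and 27.9% of Sd peaks overlapped Pol II. With lists of equal length these 4 shares were 56.6, 52.0, 32.2 and 18.8%. Fewer peaks in a target list leave fewer to meet. The share of Yki peaks with Sd rose instead, from 20.1%, since the Sd list kept its 2557 peaks and only the highest-scoring Yki peaks stayed. With peaks reduced to 200 bp the 4 shares were 75.8, 16.6, 29.2 and 18.5%, and the highest decile of Yki score overlapped Sd in 57.9%. Within deciles of Yki width, the Sd overlap was 53.7% in the highest and 6.50% in the lowest score decile. The difference in Pol II overlap between Yki peaks with and without Sd kept its sign, at -22.2 points within width deciles, -26.2 within score deciles, -10.7 with the 1 kb gap and -10.8 with 200 bp peaks. Random placement left the chance level of Sd on Yki at 7.36%. Median widths stayed within their quartiles. Alternatives for start sites, gene lists and motifs were not run, since these results were not. No paired analysis was possible because each antibody had 1 library. Read depth is unknown, so its effect on the number of peaks was not tested; a Yki peak without an Sd peak is a site where none was called, not a site shown to lack Sd.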

Other observations

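The comparisons by chromosome, the Pol II and Sd overlaps within deciles of Yki score or of width and score together, the Pol II shares expected from deciles and the random reassignment of Sd status were tests chosen after the result was seen; the Pol II comparison within width deciles was planned, and its use as a test of the last pattern was chosen afterwards. Chromosome 4, the small and largely heterochromatic chromosome, stood apart in Sd. Of its 109 Yki peaks, 46.8% had an Sd peak (exact 95% interval 37.2 to 56.6), against 19.6% of 11437 on the other arms (18.9 to 20.4). Yki peaks there also scored higher (median 29.7 against 21.6), and their score deciles alone would give 29.1%. Pol II density on chromosome 4 was 145 peaks per Mb against 82.0 on the other arms, a ratio of 1.77; for Sd the ratio was 1.91 and for Yki 0.841. Pol II overlapped 56.0% of Yki peaks on chromosome 4 (46.1 to 65.5) and 54.2% on the other arms (53.3 to 55.1).

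The X chromosome held 13 of the 25 Sd peaks tied at the highest score, or 52.0% (31.3 to 72.2), against 17.6% of all Sd peaks. In the highest decile of each list, X held 24.6% of Sd peaks (19.5 to 30.4) against 16.8% of the rest, 18.2% of Yki peaks against 18.0%, and 21.0% of Pol II peaks against 17.5%. All 25 had a Yki peak and 5 overlapped Pol II.

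A first pattern is that most Yki peaks had no Sd peak. A candidate explanation is that weaker Sd sites fell under the limit of the shorter Sd list. The Sd share in the highest decile of Yki score was 3.45 times the share over all Yki peaks, above the 3 times set in advance; within deciles of Yki width it was 2.67 times, below that bound. Of the 100 highest Yki peaks, 97 had Sd. Another explanation, Yki sites without Sd, met its bound: 29.5% of the highest decile (345 of 1168) had no Sd peak within 1 kb, above the 25% set in advance. Since that share is far lower among the 100 highest, a limit on Sd calls may produce part of it, and the lists do not separate the explanations. The discs also overexpressed Yki, and any part of this in the pattern was not tested.

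A second pattern is that Yki and Sd peaks coincide. Recovery of transcribed sites by any antibody would place the shared peaks mostly inside Pol II peaks. Instead Sd overlapped 23.4% of Yki peaks outside Pol II (22.3 to 24.6) and 17.3% inside (16.4 to 18.2), a difference of 6.11 points in the opposite direction. The same counts give the lower Pol II overlap of Yki peaks with Sd, read the other way, so this is not a separate result. Shared Yki peaks numbered 1250 outside Pol II. At these no Pol II peak was called in discs of the other genotype, which does not show that they are untranscribed. They argue against the explanation only if the Pol II list holds the sites transcribed in the Yki and Sd discs, which was not tested. For the 1095 inside, the explanation is not decided, because Yki peaks recovered there without Sd would lower the Sd share. Sd peaks also lay on Pol II in 39.8% of cases, against a shifted mean of 7.41%. For the Yki peaks on the strongest Pol II peaks, of which 95.6% carried Yki and 21.6% Sd, this explanation was not tested. Sites recovered by both antibodies for another reason also stay open, as no list from an unrelated antibody was analysed here.

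The last pattern is the lower Pol II overlap of Yki peaks with Sd, which rests on the same counts as the Sd shares inside and outside Pol II. Narrow misses beside a Pol II peak are argued against by the difference of -10.7 points with a gap of 1 kb allowed. Score and width of the Yki peaks point the other way: the Pol II share of each score decile would give 61.9% for peaks with Sd and 52.3% for those without, and that of each width decile 59.3 and 53.0%. Accordingly the difference widened to -26.2 points within score deciles and -22.2 within width deciles. Reassigning Sd status at random within score deciles gave -4.65 to 5.47 in 1000 draws. Score and width were higher with either overlap, so part of the widening can come from comparing within deciles. The random reassignment cannot detect this. Counting each decile equally, whatever its number of peaks with Sd, can add to the widening as well. As a hypothesis, Yki sites shared with Sd may more often be distal elements than promoters, which dm3 annotation would be needed to test. The genotype of the Pol II sample stays open, with 0 Pol II lists from Yki S168A discs.

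Sd peaks without Yki were 0 of 256 in the highest decile of Sd score, which allows up to 1.17% (3 counts of the total), 4 of 256 in the lowest decile and 16 of 256 in decile 5. On heterochromatic or unplaced sequence lay 0 of these 58 peaks, which allows up to 5.17% by the same limit. In the lowest decile of Sd score, 98.4% of peaks lay on a Yki peak (96.0 to 99.6).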
